A study of Mus musculus with 22 samples.

How the data were processed

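The series holds 22 RNA-seq libraries of eosinophils of maturation stages I to IV, sorted from the bone marrow of C57BL/6 wild-type mice. Per the labels' protocols, mice received 400 ng IL-33 intraperitoneally on each of 7 days and then 3 daily injections of 400 µg anti-IL5 or isotype control antibody, starting with the last IL-33 injection. Marrow was depleted with antibodies to Ly6G, CD90.2, NK1.1 and CD45R, the stages were gated on CD29, F4/80, Siglec-F, CD55, CD117, PIR-A/B and CD200R3, and sort purity was at least 95%. Each treatment has 11 libraries, 3 per stage and 2 at stage II, with replicate numbers from the sample titles. The labels do not say whether equal numbers mark 1 animal or separate animals, so each p-value measures the spread between samples, and the mean over stages treats libraries with equal numbers as independent.

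Full-length cDNA was made with SMART-Seq v4 (17 amplification cycles, a kit that does not mark strand) and turned into libraries with Nextera XT, with no molecular barcodes named, so every counting interval and floor given covers counting error alone. Per the submitters' processing notes, STAR 2.6.1a and build mm10 were used and DESeq2 is named without its role. The counting tool, annotation and strand setting are not given in the sources used here. Each deposited file holds raw counts per gene symbol, 24982 genes plus 2 lines that name no gene (no feature, 12.7% to 22.1% of all counts, and ambiguous, 1.86% to 2.39%), which stayed out of library sizes and tests. The files have 0 mitochondrial gene lines, so the mitochondrial share could not be computed. Without strand, reads of overlapping and antisense genes cannot be told apart, and near-identical copies (the Bcl2a1, Pira and Ear families) may split reads.

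CPM were computed here from the deposited counts with TMM-scaled library sizes. Libraries held 7161264 to 14781250 gene counts, with 12359 to 13829 genes seen and 4.19% to 9.48% of counts in the 10 most abundant genes. The floor of 3 counts equals 0.203 to 0.419 CPM per library. Exact permutation tests between treatments within each stage on totals, genes seen and the share of the 10 most abundant genes can give no p below 0.1 with 3 against 3 (0.333 with 2 against 2). Genes seen at stage I (13220 ± 58 under anti-IL5, 13500 ± 285 in isotype libraries) and the share of the 10 most abundant at stage III (5.301% ± 0.329 and 6.602% ± 0.515) reached exact permutation p = 0.1. A search for copied libraries found none. Of 16619 genes with at least 1 count, filterByExpr kept 12387.

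Choices of tests, gene lists, the rule for named genes and the alternatives were made before the data were examined, apart from those said to have been added. All 22 libraries were fitted in 1 edgeR 4.0.16 quasi-likelihood model (R 4.3.3, TMM, robust dispersion) with 8 groups of stage and treatment, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Contrasts were anti-IL5 against isotype at each stage and averaged over stages, each maturation step within each treatment, the difference of the treatment effect between adjacent stages, and the stage by treatment interaction. In tests of small groups the lone or paired libraries borrow spread from the other groups. Log2 CPM for principal components and the axis used a prior count of 2.

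Of 28 gene lists, 27 had at least 3 tested genes and were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated per list. They cover granule proteins, receptors and effectors, sort markers, stem and progenitor genes, transcription factors, S and G2/M phase, ribosome biogenesis, the secretory pathway with the unfolded protein response, IL-5/STAT5 targets, pro- and antiapoptotic genes, interferon response, IL-33/NF-kB, glycolysis, cholesterol synthesis, cytosolic ribosomal proteins, oxidative phosphorylation, sex-linked genes and 9 other cell types (azurophil and mature neutrophil, monocyte, basophil and mast cell, erythroid, megakaryocyte, B lineage, dendritic, and T, NK and innate lymphoid cells, the last given as summed CPM only).

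Named genes follow a rule: (a) among called genes with a mean of at least 10 CPM in the higher group and no overlap between the libraries of both groups, leaving out predicted and pseudogene symbols, the 8 largest rises and 8 largest falls (5 and 5 for anti-IL5 steps, the mean over stages and differences); (b) up to 4 members of each called list; (c) for treatment, receptor, STAT5, survival and granule genes fixed by name; (d) where fewer than 5 pass, those of smallest p. For differences of the treatment effect between stages, part (a) did not ask for libraries without overlap. With 3 against 3 libraries, 10% of genes separate by chance. At stage I 28.4% did, at stage III 26% and at stage IV 15.8%. Groups with 1 to 3 counts get a ratio with its 95% counting interval, and groups with 0 counts a bound against 3 counts over the group. Positions are GRCm38, from RefSeq names matched to GENCODE M21.

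The maturation axis ran between the mean log2 CPM of neighbouring stages over both treatments, and library positions were compared by exact permutation. Alternatives tried were median-ratio and upper-quartile scaling, no filter, a filter of 10 CPM in 2 libraries, DESeq2 1.42.0, limma-voom 3.58.1 with sample quality weights, a replicate block, a random replicate block, glmTreat against a fold of 1.5, only the 2 groups compared, each library left out in turn, fry, a prior count of 0.5, stage-differing genes only and no cell cycle genes. Of the comparisons with 3 pairs of same-numbered libraries, deviations from group means correlated above 0.1 in every pair for stages III and IV in isotype mice (0.12 to 0.21), so the numbers pair the samples there by the rule set. With 2 pairs, too few for the rule, they did so between treatments at stage II (0.34) and for stages I and II under anti-IL5 (0.13 to 0.16). On simulated data with 200 genes changed at each of 2 folds, edgeR recovered 56% to 76% of 2-fold and 98.5% to 100% of 4-fold changes within single stages, with 4.9% to 5.39% false calls. The mean over stages, with 100 genes changed at each fold among 11587, had 12.4% false calls. Simulated lowering of 1 list was called with 0 of 26 other lists.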

Results

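Eosinophils of 4 maturation stages, from stage I (earliest) to stage IV, were sorted from the bone marrow of mice given IL-33 and then either an antibody against IL-5 or its isotype control. The first principal component of the 22 libraries held 62.3% of the variance and followed maturation, running from -115 ± 5.67 (mean ± SD) at stage I to 115 ± 1.43 at stage IV in isotype mice. On this component anti-IL5 libraries lay toward the later stages at stage I (-99.5 ± 5.12), stage II (-52.4 ± 5.1 against -78.5 ± 6.18) and stage III (55.3 ± 10.9 against 16.9 ± 12.9), and level with isotype libraries at stage IV (114 ± 2.14). Below, "log2" stands before a log2 fold change ± SE, CPM are means ± SD over libraries (n = 3 per group, n = 2 at stage II), and a library is named by its treatment and replicate number. Where leaving out 1 library ended a call, brackets after the gene give the highest edgeR adjusted p of these fits. Ranks such as "furthest" or "largest" are among called genes with a mean of at least 10 CPM in the higher group and no overlap between libraries.

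**Figure D1:**
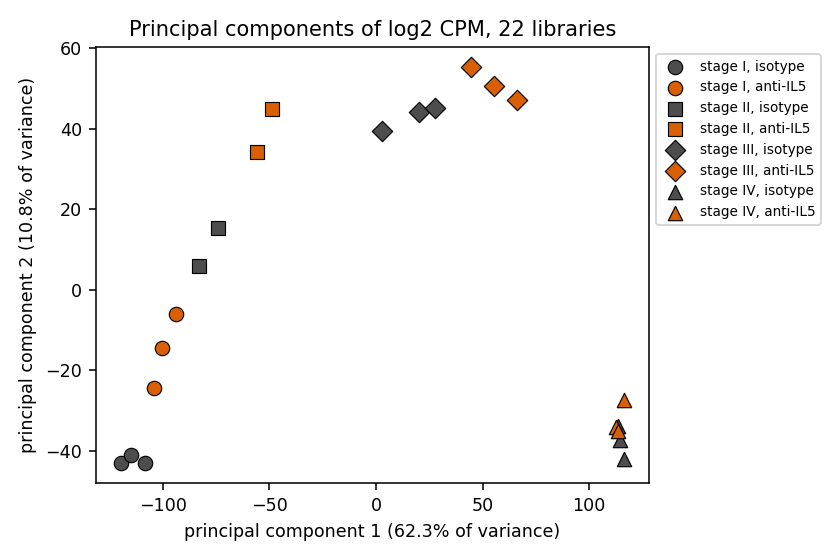
Principal components of the 22 libraries from log2 CPM of the genes tested, coloured by treatment and with a marker for each stage.

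At stage I, Lipg, an endothelial-type lipase, fell furthest under anti-IL5 (log2 -7.12±0.74, 0.518±0.738 against 77.2±16.2 CPM, edgeR adjusted p=1.37e-06). It was followed by Socs2, a feedback inhibitor of cytokine signalling induced by STAT5 (log2 -5.15±0.61, 0.403±0.416 against 14.9±2.11 CPM, edgeR adjusted p=1.74e-05), and Crhbp, the binding protein of corticotropin-releasing hormone (log2 -4.53±0.47, 4.6±2.63 against 106±24.6 CPM, adjusted p=2.05e-05). Cyp11a1, the enzyme that starts steroid synthesis, fell as well (log2 -2.50±0.38, edgeR adjusted p=0.000992). So did the protease inhibitor Serpina3g (log2 -2.61±0.55), the potassium channel Kcnk5 (log2 -2.48±0.67), Ifitm1 (log2 -2.23±0.49) and the transglutaminase Tgm1 (log2 -2.16±0.60). Tgfbi, a secreted matrix protein, rose most (log2 3.31±0.28, 44.9±12.3 against 4.47±1.06 CPM, edgeR adjusted p=8.68e-07). Id2, an inhibitor of basic helix-loop-helix factors, rose (log2 2.85±0.17, 248±51.8 against 34.2±7.44 CPM, edgeR adjusted p=3.01e-09). Ccr3, the eotaxin receptor, rose (log2 2.41±0.41, 26.6±8.57 against 4.89±2.19 CPM, edgeR adjusted p=0.00183). The Src-family kinase Fgr (log2 2.59±0.31), Retnlg (log2 2.53±0.33), the leukocyte receptor Lilra6 (log2 2.52±0.33), the metalloproteinase Mmp25 (log2 2.49±0.35) and Serpinb2 (log2 2.38±0.45) rose too.

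Of the gene lists, ribosome biogenesis fell at stage I (18 of 40 lower, 32 lower over the list alone, camera adjusted p=2.82e-24 and 0.00162 with an estimated correlation), with Heatr1 (log2 -1.34±0.28) and Rrp1b (log2 -1.06±0.20) among its lower members. The secretory pathway and unfolded protein response fell (16 of 32 lower, 24 lower over the list alone, camera adjusted p=1.32e-20 and 0.00357 with an estimated correlation), for example the disulfide isomerase Pdia4 (420±72.2 against 902±121 CPM, edgeR adjusted p=0.00347). The other list calls were lost with an estimated correlation. Receptors and effectors were higher (4 of 26 higher, 6 higher over the list alone, camera adjusted p=0.00246 and 0.306 with an estimated correlation): Ccr3, Pirb (log2 1.64±0.22), Itgam (log2 1.01±0.23) and Cd9 (log2 0.95±0.22) rose. Eosinophil transcription factors were higher (2 of 19 higher, 2 higher over the list alone, camera adjusted p=0.00494 and 0.201 with an estimated correlation): Id2 and Id1 (log2 1.83±0.26) rose. G2/M genes were higher (3 of 52 higher, 10 higher over the list alone, camera adjusted p=1.29e-11 and 0.306 with an estimated correlation): Ndc80 (log2 1.02±0.20), Cdc20 (log2 0.73±0.20) and Hmgb2 (log2 0.55±0.15) rose. Mature neutrophil genes were higher (1 of 14 higher, 3 higher over the list alone, camera adjusted p=0.000783 and 0.481 with an estimated correlation), the member called being Retnlg. Cholesterol synthesis was lower (0 of 22 by edgeR, 8 lower at an unadjusted p under 0.05, 0 over the list alone, camera adjusted p=0.00224 and 0.201 with an estimated correlation). Cytosolic ribosomal proteins were lower (0 of 82 by edgeR, 35 lower at an unadjusted p under 0.05, 0 over the list alone, camera adjusted p=1.13e-13 and 0.481 with an estimated correlation). Oxidative phosphorylation was lower (1 of 77 lower, 0 over the list alone, camera adjusted p=0.000783 and 0.737 with an estimated correlation).

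IL-5/STAT5 targets went both ways at stage I: Pim1, a survival kinase (log2 -2.12±0.29), Socs1 (log2 -1.88±0.29) and Socs2 fell while Bcl6 (log2 2.50±0.51) and Id1 rose. The list had no call (2 of 23 higher and 3 lower, 4 higher and 4 lower over the list alone, camera adjusted p=0.403 and 0.741 with an estimated correlation). Alox15, the 15-lipoxygenase of eosinophils, rose (log2 1.65±0.23, 1780±587 against 567±57.2 CPM), while the granule genes Epx (log2 -0.29±0.33, edgeR adjusted p=0.713) and Prg2 (log2 0.22±0.28, adjusted p=0.759) did not pass the test. The IL-5 receptor chain Il5ra had log2 0.20 (edgeR adjusted p = 0.645) and the proliferation marker Mki67 log2 0.71 (adjusted p = 0.215). The antiapoptotic Bcl2a1a fell (log2 -2.04±0.39), but reads may be split with its near-identical copies Bcl2a1b and Bcl2a1d. Of the sort markers, Pira2 (log2 2.53±0.76) and Pirb were higher and Cd55 was lower (log2 -1.06±0.21). In all, 323 genes were higher and 225 lower by edgeR (548 of 12387; 2242 at an unadjusted p under 0.05), against 775 and 919 by limma-voom, which moved the share of higher calls from 58.9% to 45.7%. The count was 184 without isotype 2, 188 higher and 121 lower without isotype 3, 255 without anti-IL5 1 and 255 without anti-IL5 2. Serpina3g (0.0752) lost the call without anti-IL5 1 or 2. Kcnk5 (0.21) did not pass without isotype 1 or 2 or 3 or anti-IL5 2 or 3. Ifitm1 (0.084) and Itgam (0.12) lost the call without isotype 2 or 3 or anti-IL5 1 or 2. Tgm1 (0.162) and Cdc20 (0.173) did not pass without any 1 of the 6 libraries. Cd9 (0.117) lost the call without isotype 2 or anti-IL5 3. Hmgb2 (0.139) did not pass without isotype 1 or 2 or anti-IL5 1 or 2. Pira2 (0.147) lost the call without isotype 2 or 3 or anti-IL5 1 or 3.

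**Figure D2:**
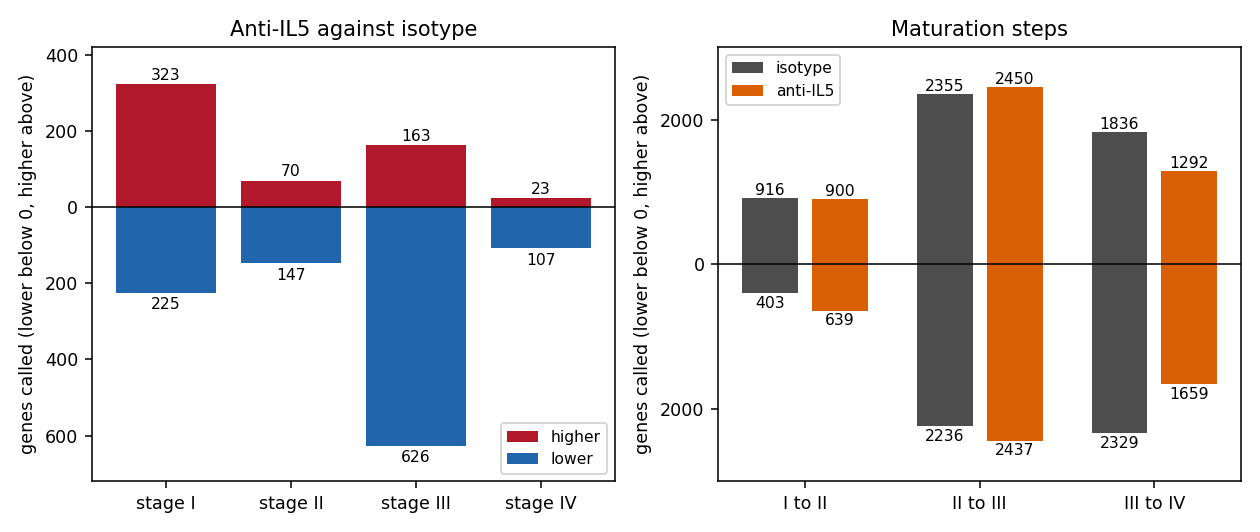
Genes called higher (above 0) and lower (below 0) at an edgeR adjusted p under 0.05 in each comparison. Treatment is on the left and maturation steps are on the right.

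At stage II, Lipg again fell most under anti-IL5 (log2 -8.27±0.93, 0.524±0.74 against 178±118 CPM, edgeR adjusted p=1.56e-05). Crhbp fell (log2 -5.89±0.77, 0.887±0.366 against 52.4±6.2 CPM, edgeR adjusted p=0.000183). Socs2 had 2 counts in anti-IL5 against 220 in isotype libraries, a 119-fold lower level with a 95% counting interval of 32.4 to 986. The survival kinase Pim1 fell (log2 -2.46±0.36, 15.3±2.28 against 84.4±18.7 CPM, edgeR adjusted p=0.00161). Other falls were the ER retention receptor Kdelr3 (log2 -4.37±0.87), Phgdh, the first enzyme of serine synthesis (log2 -3.16±0.60), the adenosine receptor Adora2b (log2 -3.14±0.64), Grm6 (log2 -3.06±0.61) and Lrp12 (log2 -2.98±0.66). Serpinb10, an intracellular serine protease inhibitor, rose furthest (log2 3.81±0.61, 16±3.01 against 1.14±0.328 CPM, edgeR adjusted p=0.00284). It was followed by Gbp9 (log2 3.49±0.77), the ubiquitin ligase March1 (log2 2.50±0.59), Tinagl1 (log2 2.27±0.47), Plbd1 (log2 2.08±0.47), Retnlg (log2 2.02±0.35) and Gcnt2 (log2 1.98±0.44). Id2 rose (log2 1.56±0.20, 828±25.5 against 280±49.1 CPM, edgeR adjusted p=0.000364).

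Ribosome biogenesis fell at stage II (15 of 40 lower, 25 lower over the list alone, camera adjusted p=3.22e-27 and 0.000792 with an estimated correlation), for example the nucleolar Gnl3 (log2 -1.93±0.28, 16.5±6.01 against 62.6±3.96 CPM). So did the secretory list (16 of 32 lower, 22 lower over the list alone, camera adjusted p=2.07e-24 and 0.0018 with an estimated correlation), for example the ER chaperone Calr (log2 -1.58±0.29, 356±108 against 1060±621 CPM). Myc, the growth regulator, fell (log2 -2.28±0.41). So did the STAT5 target Cish (log2 -2.18±0.46), Cyp11a1 (log2 -2.65±0.47) and Bcl2a1a (log2 -2.11±0.43), while Bcl6 rose (log2 2.69±0.63). The other list calls at stage II were lost with an estimated correlation. Cytosolic ribosomal proteins were lower (2 of 82 lower, 36 lower over the list alone, camera adjusted p=1.52e-20 and 0.394 with an estimated correlation): Rpl12 fell (log2 -1.14±0.27). S phase genes were lower (1 of 42 lower, 1 lower over the list alone, camera adjusted p=0.00688 and 0.394 with an estimated correlation). Basophil and mast cell genes were lower (1 of 9 lower, 2 lower over the list alone, camera adjusted p=0.0482 and 0.42 with an estimated correlation): Cyp11a1 fell. Receptors and effectors were higher (1 of 26 higher, 2 higher over the list alone, camera adjusted p=0.0155 and 0.394 with an estimated correlation): Cd80 rose (36 counts against 2, 16.7-fold higher, 95% counting interval 4.3 to 143). Transcription factors were higher (1 of 19 higher and 1 lower, 3 higher and 1 lower over the list alone, camera adjusted p=0.024 and 0.317 with an estimated correlation): Id2 rose and Xbp1 fell (log2 -0.83±0.16). G2/M genes were higher (0 of 52 by edgeR, 5 higher at an unadjusted p under 0.05, 0 over the list alone, camera adjusted p=4.37e-07 and 0.412 with an estimated correlation). Interferon response genes were higher (0 of 30 by edgeR, 5 higher at an unadjusted p under 0.05, 0 over the list alone, camera adjusted p=5.12e-05 and 0.54 with an estimated correlation). Cholesterol synthesis was lower (0 of 22 by edgeR, 6 lower at an unadjusted p under 0.05, 6 lower over the list alone, camera adjusted p=0.00139 and 0.178 with an estimated correlation). B lineage genes were higher (0 of 6 by edgeR, 1 higher at an unadjusted p under 0.05, 0 over the list alone, camera adjusted p=0.0242 and 0.293 with an estimated correlation).

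Il5ra (log2 -0.19±0.23, adjusted p=0.801), Ccr3 (log2 1.31±0.44, adjusted p=0.166), Epx (log2 -0.67±0.40, adjusted p=0.514) and Prg2 (log2 -0.16±0.34, adjusted p=0.903) did not pass the test at stage II. By edgeR 70 genes were higher and 147 lower (217; 1678 at an unadjusted p under 0.05). The count was 423 without isotype 1 (251 higher and 172 lower, so the excess of falls turned), 40 without isotype 2, 57 without anti-IL5 1 and 62 without anti-IL5 2, and of the genes named above Lipg, Socs2, Crhbp, Id2, Pim1 and Gnl3 passed in each of these 4 fits. Serpinb10 (0.0567) lost the call without isotype 2. Gbp9 (0.176), Tinagl1 (0.225), Retnlg (0.0581), Kdelr3 (0.125), Phgdh (0.146) and Calr (0.174) did not pass without isotype 2 or anti-IL5 1. March1 (0.139), Gcnt2 (0.147), Cd80 (0.199) and Bcl6 (0.0938) lost the call without any 1 of the 4 libraries. Plbd1 (0.24), Lrp12 (0.184) and Rpl12 (0.168) did not pass without isotype 2 or anti-IL5 1 or 2. Adora2b (0.147), Grm6 (0.133) and Bcl2a1a (0.118) lost the call without isotype 1 or anti-IL5 1 or 2. Myc (0.0899) and Cish (0.151) did not pass without isotype 2 or anti-IL5 2. Cyp11a1 (0.0937) lost the call without anti-IL5 1 or 2. Xbp1 (0.112) did not pass without isotype 1 or anti-IL5 2.

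At stage III, the S phase, ribosome biogenesis, secretory, cholesterol and basophil and mast cell lists fell under anti-IL5, along with the granule peroxidase Epx. Lipg was almost absent, with 2 counts against 4868, a 2710-fold lower level (95% counting interval 750 to 22400) from 171 ± 22 CPM in isotype libraries. Crhbp (log2 -6.27±0.93), Kdelr3 (log2 -5.94±0.93), Tgm1 (log2 -5.23±0.84), the heparan sulfate enzyme Hs3st1 (log2 -4.59±0.65), Lrp12 (log2 -4.58±0.55), Adora2b (log2 -4.36±0.51, 5.1±3.5 against 104±6.62 CPM, edgeR adjusted p=0.000105) and Socs2 (log2 -4.34±0.56, 0.543±0.26 against 11.1±4.11 CPM) fell. Epx, the eosinophil peroxidase, fell (log2 -1.56±0.33, 4700±1410 against 13900±1670 CPM, edgeR adjusted p=0.00653). Prg3, a granule basic protein, fell (log2 -1.21±0.26, 1640±383 against 3800±802 CPM), while Prg2 did not pass (log2 -0.58±0.28, edgeR adjusted p=0.228). Serpinb10 rose most (log2 4.56±0.46, 38.3±5.4 against 1.66±0.952 CPM, edgeR adjusted p=1.05e-05). Tgm2, the tissue transglutaminase, rose (log2 2.17±0.36, 74.8±9.51 against 16.6±4.46 CPM, edgeR adjusted p=0.00141). Other rises were Pbld1 (log2 2.58±0.49), Atp8b5 (log2 2.06±0.44), Miox (log2 1.96±0.48), Lsp1 (log2 1.83±0.40), Cd80 (log2 1.82±0.48) and Id2 (log2 0.87±0.16, 987±11.4 against 541±10.1 CPM).

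**Figure D3:**
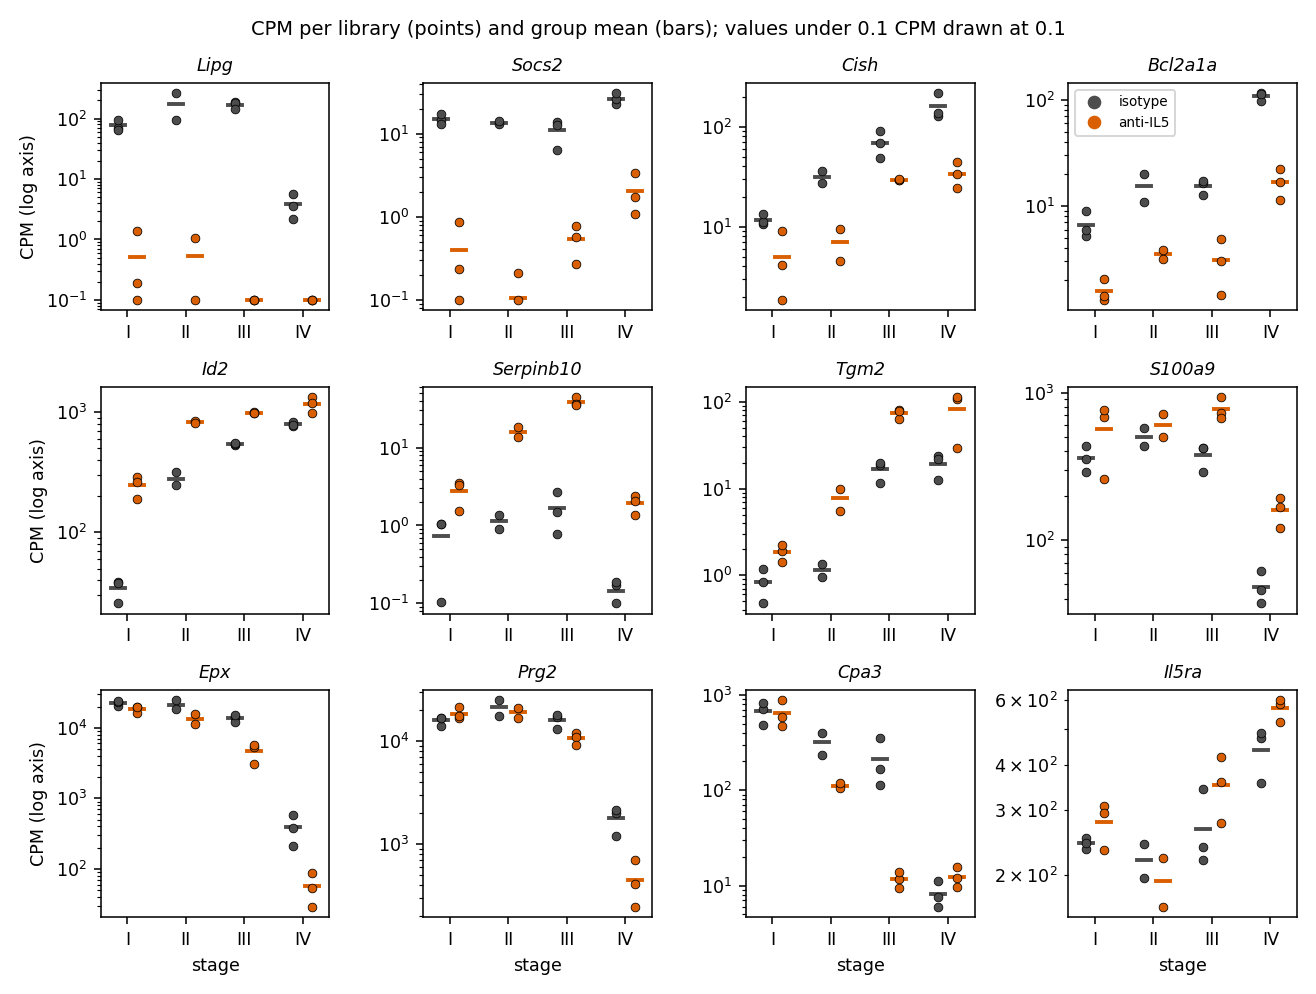
CPM of single libraries (points) and group means (bars) for 12 genes by stage and treatment, on log axes. Values below 0.1 CPM are drawn at 0.1.

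S phase genes fell at stage III (23 of 42 lower, 32 lower over the list alone, camera adjusted p=4.32e-28 and 0.000511 with an estimated correlation), for example the replication helicase subunit Mcm3 (log2 -1.51±0.21, 61.5±14.4 against 175±19.8 CPM). Ribosome biogenesis fell (19 of 40 lower, 24 lower over the list alone, camera adjusted p=4.12e-15 and 0.00495 with an estimated correlation). The secretory list fell (14 of 32 lower, 20 lower over the list alone, camera adjusted p=5.71e-17 and 0.00495 with an estimated correlation), for example the chaperone Sdf2l1 (log2 -2.05±0.20, 40.6±8.58 against 168±34.5 CPM). Cholesterol synthesis fell (10 of 22 lower, 12 lower over the list alone, camera adjusted p=2.33e-08 and 0.00495 with an estimated correlation), for example Fdps, which makes farnesyl pyrophosphate (log2 -1.44±0.22). Basophil and mast cell genes fell (6 of 9 lower, 7 lower over the list alone, camera adjusted p=8.76e-12 and 0.00576 with an estimated correlation). They include the mast cell carboxypeptidase Cpa3 (log2 -4.18±0.35, 11.7±2.34 against 212±126 CPM, edgeR adjusted p=3.43e-06), the IgE receptor chain Ms4a2 (log2 -3.07±0.55) and Cyp11a1 (log2 -3.02±0.39). Xbp1, a transcription factor that eosinophil precursors need (log2 -1.31±0.13, 104±7.2 against 259±29.1 CPM), Gata2 (log2 -1.53±0.22) and Myc (log2 -2.56±0.40) fell. The other list calls were lost with an estimated correlation. Granule proteins were lower (2 of 11 lower, 3 lower over the list alone, camera adjusted p=0.0287 and 0.585 with an estimated correlation). G2/M genes were lower (7 of 52 lower, 16 lower over the list alone, camera adjusted p=5.09e-09 and 0.414 with an estimated correlation). Receptors and effectors were higher (2 of 26 higher, 3 higher and 1 lower over the list alone, camera adjusted p=0.0156 and 0.442 with an estimated correlation): Cd80 and the integrin Itga4 (log2 0.75±0.21) rose. Oxidative phosphorylation was lower (2 of 77 lower, 0 over the list alone, camera adjusted p=0.0317 and 0.742 with an estimated correlation). Mature neutrophil genes were higher (1 of 14 higher, 3 higher over the list alone, camera adjusted p=4.87e-05 and 0.414 with an estimated correlation): S100a9 rose (log2 1.04±0.29). IL-5/STAT5 targets had no list call (2 of 23 higher and 6 lower, 3 higher and 7 lower over the list alone, camera adjusted p=0.0912 and 0.672 with an estimated correlation). Antiapoptotic genes had none either (1 of 14 higher and 3 lower, 2 higher and 7 lower over the list alone, camera adjusted p=0.0912 and 0.59 with an estimated correlation). Single members fell: Bcl2a1a (log2 -2.29±0.34), Pim1 (log2 -1.17±0.28) and Bcl2l1 (log2 -0.83±0.24).

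Il5ra (log2 0.40±0.18, adjusted p=0.214), Ccr3 (log2 0.82±0.35, adjusted p=0.172), Siglecf (log2 0.05±0.14, adjusted p=0.878) and Mki67 (log2 -0.99±0.31, adjusted p=0.0592) did not pass at stage III. The totals were 163 genes higher and 626 lower by edgeR (789; 2688 at an unadjusted p under 0.05), with 339 without isotype 3, 489 without anti-IL5 2 and 36 higher and 272 lower without anti-IL5 3. Epx (0.0572), Atp8b5 (0.0529) and Lsp1 (0.0574) lost the call without anti-IL5 3. Prg3 (0.0637) did not pass without isotype 3 or anti-IL5 3. Miox (0.0629) lost the call without isotype 1 or 2 or 3 or anti-IL5 2 or 3. Cd80 (0.106) did not pass without isotype 1 or 3 or anti-IL5 2 or 3. Itga4 (0.177) lost the call without isotype 2 or 3 or anti-IL5 2 or 3. S100a9 (0.163) did not pass without any 1 of the 6 libraries. Pim1 (0.0754) lost the call without isotype 1 or anti-IL5 2 or 3. Bcl2l1 (0.162) did not pass without isotype 1 or 2 or anti-IL5 2 or 3.

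At stage IV, the granule, IL-5/STAT5 and antiapoptotic lists, which may share genes, fell under anti-IL5. Epx fell (log2 -2.79±0.33, 56.4±29.2 against 389±188 CPM, edgeR adjusted p=0.000175). Prg2, the major basic protein, fell (log2 -1.99±0.28, 452±231 against 1790±517 CPM, edgeR adjusted p=0.000576). The ribonuclease Ear6 (log2 -2.58±0.33) and Cst7 (log2 -1.01±0.15) fell. These are the members called in the granule list (4 of 11 lower, 5 lower over the list alone, camera adjusted p=1.33e-14 and 0.00969 with an estimated correlation). The IL-5/STAT5 list fell (8 of 23 lower, 1 higher and 12 lower over the list alone, camera adjusted p=3.36e-15 and 0.00535 with an estimated correlation). Its members include Cish (log2 -2.24±0.34, 34±10.1 against 161±47.6 CPM, edgeR adjusted p=0.00153), Socs2 (log2 -3.72±0.45, 2.04±1.17 against 26.4±4.04 CPM, adjusted p=0.000175) and Cdkn1a (log2 -2.66±0.53). The antiapoptotic list fell (6 of 14 lower, 8 lower over the list alone, camera adjusted p=8.29e-13 and 0.00535 with an estimated correlation). Its members include Bcl2 (log2 -2.23±0.40, 1.84±0.857 against 8.61±3.31 CPM, edgeR adjusted p=0.00386), Bcl2a1a (log2 -2.68±0.31, 16.8±5.51 against 108±9.94 CPM, adjusted p=0.000108), Bcl2a1b (log2 -2.04±0.44), Bcl2a1d (log2 -3.09±0.71) and Bcl2l1 (log2 -1.13±0.24). The Bcl2a1 copies may repeat the same signal. Cholesterol synthesis fell (2 of 22 lower, 6 lower over the list alone, camera adjusted p=7.67e-07 and 0.0137 with an estimated correlation), for example Mvd (log2 -1.11±0.23).

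Adora2b fell most at stage IV (log2 -5.40±0.55, 2.73±2.82 against 110±28.5 CPM, edgeR adjusted p=0.000102). Other falls were Prr5l (log2 -5.40), Enah (log2 -4.57±0.55), the adrenergic receptor Adra2a (log2 -4.22±0.65), Plxdc2 (log2 -3.98), Fam160a1 (log2 -3.79±0.72) and Ecm1 (log2 -3.67±0.68). Dhrs3, a retinaldehyde reductase, rose most (log2 2.59±0.37, 29.8±17.3 against 4.93±0.983 CPM, edgeR adjusted p=0.000699). Other rises were the cytokine Il15 (log2 2.46±0.37), Sntb1 (log2 2.12±0.25), Tgm2 (log2 2.11±0.36), S100a9 (log2 1.75±0.30, 161±36.5 against 48±12.3 CPM), Rnf43 (log2 1.58±0.24), the neutrophil granule gene Ngp (log2 1.39±0.30) and Lbp (log2 1.39±0.22). The other list calls at stage IV were lost with an estimated correlation. Mature neutrophil genes were higher (2 of 14 higher, 4 higher over the list alone, camera adjusted p=9.71e-09 and 0.168 with an estimated correlation): S100a9 and Ngp rose. Transcription factors were lower (2 of 19 lower, 1 higher and 3 lower over the list alone, camera adjusted p=0.0191 and 0.231 with an estimated correlation): Xbp1 (log2 -1.46±0.13) and Id1 (log2 -1.45±0.27) fell. Interferon response genes were higher (1 of 30 higher, 1 higher over the list alone, camera adjusted p=0.00506 and 0.646 with an estimated correlation). The listed genes summed to 1190, 1320 and 3280 CPM in isotype libraries 1 to 3 and to 2660, 2200 and 2270 CPM in anti-IL5 libraries. Glycolysis was lower (1 of 18 lower, 3 lower over the list alone, camera adjusted p=0.00167 and 0.231 with an estimated correlation): Pgam1 fell (log2 -0.62±0.14). Azurophil and precursor genes were higher (1 of 8 higher, 1 higher over the list alone, camera adjusted p=0.0011 and 0.231 with an estimated correlation): Gfi1 rose (log2 1.38±0.19). The secretory list was lower (1 of 32 lower, 1 lower over the list alone, camera adjusted p=0.00447 and 0.323 with an estimated correlation), Xbp1 being the member called. Ribosome biogenesis was lower (0 of 40 by edgeR, 1 higher and 2 lower at an unadjusted p under 0.05, 0 over the list alone, camera adjusted p=0.00685 and 0.323 with an estimated correlation). Cytosolic ribosomal proteins were higher (0 of 82 by edgeR, 7 higher at an unadjusted p under 0.05, 0 over the list alone, camera adjusted p=8.02e-07 and 0.596 with an estimated correlation). G2/M genes were higher (0 of 52 by edgeR, 6 higher at an unadjusted p under 0.05, 0 over the list alone, camera adjusted p=0.000703 and 0.558 with an estimated correlation).

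Siglecf (log2 -0.51±0.14, adjusted p=0.0858), Il5ra (log2 0.37±0.18, adjusted p=0.559), Csf2rb (log2 -0.69±0.19, adjusted p=0.106), Ccr3 (log2 0.25±0.35, adjusted p=0.947) and Pim1 (log2 -0.93±0.28, adjusted p=0.145) did not pass at stage IV. By edgeR 23 genes were higher and 107 lower (130; 1139 at an unadjusted p under 0.05), with 68 without isotype 2, 80 without anti-IL5 2 and 82 without anti-IL5 3. Ngp (0.129) and Bcl2a1b (0.165) lost the call without isotype 1 or 2 or 3 or anti-IL5 2 or 3. Plxdc2 (0.143) did not pass without isotype 2 or 3 or anti-IL5 1 or 2 or 3. Fam160a1 (0.0771) lost the call without anti-IL5 2 or 3. Ecm1 (0.0651) did not pass without anti-IL5 2. Id1 (0.0543) lost the call without isotype 2 or anti-IL5 3. Cdkn1a (0.133) did not pass without isotype 3 or anti-IL5 2 or 3. Bcl2a1d (0.2) lost the call without any 1 of the 6 libraries. Bcl2l1 (0.139) did not pass without isotype 2 or anti-IL5 2 or 3. Pgam1 (0.186) lost the call without isotype 2 or 3 or anti-IL5 1 or 3. Mvd (0.0901) did not pass without isotype 2 or 3 or anti-IL5 2 or 3.

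Averaged over the 4 stages, 1065 genes were higher and 1278 lower under anti-IL5 by edgeR, a test that treats libraries with the same number as independent. Of the falls, 5 were called at every stage, in different libraries each time: Bcl2a1a, Lipg (log2 -8.05±0.70, chromosome 18, 74939322 to 74961263), Lrp12 (log2 -3.20±0.27, chromosome 15, 39870589 to 39944015), Man2a2 and Socs2 (log2 -4.99±0.38, chromosome 10, 95383903 to 95417321). Serpinb10 (log2 3.47±0.31, chromosome 1, 107528994 to 107560742) and Sntb1 (log2 1.79±0.13, chromosome 15, 55636388 to 55907302) rose at every stage. The other members of the 5 largest mean changes each way were Tgm2 (log2 2.03±0.25), Atp8b5 (log2 1.95±0.27), Dhrs3 (log2 1.73±0.19), Adora2b (log2 -3.61±0.29, chromosome 11, 62248984 to 62266452) and Tgm1 (log2 -3.23±0.35). Epx (log2 -1.33±0.17, edgeR adjusted p=2.61e-05, chromosome 11, 87863997 to 87875536) and Prg2 (log2 -0.63±0.15, adjusted p=0.00453, chromosome 2, 84980461 to 84983632) fell. Cish (log2 -1.72±0.19, edgeR adjusted p=4.63e-06), Pim1 (log2 -1.67±0.15, adjusted p=3.67e-07), Bcl2 (log2 -0.66±0.18, adjusted p=0.0122), Bcl2l1 (log2 -0.66±0.13, adjusted p=0.00114) and Xbp1 (log2 -0.97±0.07, adjusted p=1.24e-08) fell. Id2 (log2 1.46±0.09, edgeR adjusted p=8.46e-10, chromosome 12, 25093799 to 25096092) and Ccr3 (log2 1.20±0.19, adjusted p=0.000235, chromosome 9, 124017825 to 124031692) rose. The receptor chains moved little: Csf2rb fell (log2 -0.38±0.10, edgeR adjusted p=0.0111) and Csf2ra rose (log2 0.42±0.11, adjusted p=0.0112). Il5ra (log2 0.19±0.10, edgeR adjusted p=0.181), Siglecf (log2 -0.02±0.07, adjusted p=0.882), Il1rl1 (log2 -0.31±0.16, adjusted p=0.191) and Mki67 (log2 -0.07±0.17, adjusted p=0.842) did not pass. The Csf2ra call ended without stage II anti-IL5 1 (edgeR adjusted p = 0.0559).

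Lower calls were shared between stages more often than independent lists would share: 78 genes between stages I and II (2.67 by chance), 102 between II and III (7.43) and 35 between III and IV (5.41), with 43 (1.83), 33 (0.921) and 7 (0.303) for higher calls. Ribosome biogenesis fell over the stages (35 of 40 lower, 37 lower over the list alone, camera adjusted p=4.75e-28 and 0.000694 with an estimated correlation). The secretory list fell (23 of 32 lower, 24 lower over the list alone, camera adjusted p=3.84e-27 and 0.00107 with an estimated correlation). Cholesterol synthesis fell (12 of 22 lower, 1 higher and 13 lower over the list alone, camera adjusted p=2.09e-08 and 0.00658 with an estimated correlation). Over the stages 11 further lists were called with the preset correlation and lost with an estimated one. Granule proteins were lower (1 of 11 higher and 5 lower, 1 higher and 5 lower over the list alone, camera adjusted p=0.0019 and 0.345 with an estimated correlation). IL-5/STAT5 targets were lower (5 of 23 higher and 8 lower, 6 higher and 10 lower over the list alone, camera adjusted p=0.00032 and 0.187 with an estimated correlation). Antiapoptotic genes were lower (2 of 14 higher and 8 lower, 3 higher and 9 lower over the list alone, camera adjusted p=0.000339 and 0.136 with an estimated correlation). Mature neutrophil genes were higher (7 of 14 higher, 10 higher over the list alone, camera adjusted p=7.66e-07 and 0.197 with an estimated correlation). By camera with the preset and then the estimated correlation, S phase (adjusted p=4.32e-06 and 0.109), basophil and mast cell (adjusted p=8.4e-05 and 0.122), cytosolic ribosomal (adjusted p=3.02e-07 and 0.578) and oxidative phosphorylation genes (adjusted p=0.0286 and 0.866) were lower. By camera in that order, receptors and effectors (adjusted p=0.0151 and 0.392), G2/M (adjusted p=0.00658 and 0.626) and interferon response genes (adjusted p=0.000846 and 0.578) were higher.

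**Figure D4:**
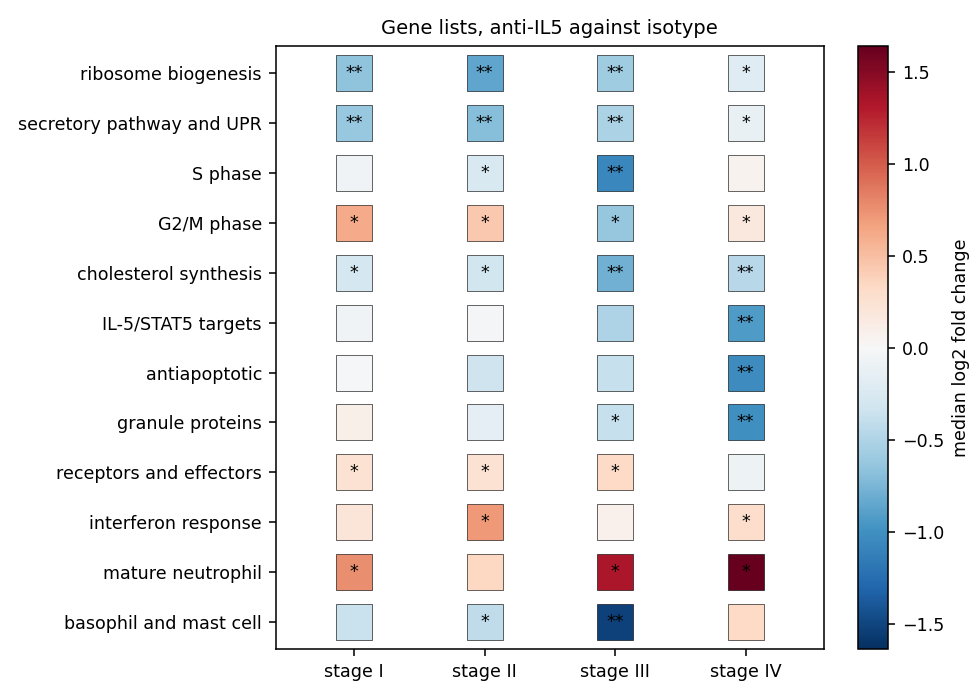
Median log2 fold change of the members of 12 gene lists under anti-IL5, by stage. One asterisk marks a camera adjusted p under 0.05 with the preset correlation and a double asterisk one that also holds with an estimated correlation.

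In isotype mice, from stage I to stage II, Alox15 (log2 2.91±0.26, 4260±1330 against 567±57.2 CPM, edgeR adjusted p=3.42e-07), Ccr3 (log2 3.35±0.44, 50.9±27.9 against 4.89±2.19 CPM), the inhibitory receptor Pirb (log2 2.71±0.25) and Id2 (log2 3.03±0.19) rose. The largest rises were Adam19 (log2 7.46±1.04), Serpinb2 (log2 6.22±0.46), Retnlg (log2 4.94±0.35), the IL-1 antagonist Il1rn (log2 4.66±0.79), the calcium-binding S100a6 (log2 4.63±0.32), Lilra6 (log2 4.02±0.35), Cd200r4 (log2 3.81±0.46) and Ifitm6 (log2 3.69±0.35). The cyclin Ccnd2 (log2 -3.13±0.50), the myeloperoxidase Mpo (log2 -3.80±0.90, 216±22 against 3010±735 CPM) and the neutrophil protease Ctsg (log2 -4.24±0.75) fell. So did Lrrn3 (log2 -4.44), Amigo2 (log2 -4.41±0.96), Bhlha15 (log2 -4.27±1.16), Serpina3g (log2 -3.98±0.64), Rab38 (log2 -3.84±0.73) and Dmkn (log2 -3.62±0.85). Epx was level (log2 -0.07±0.36, edgeR adjusted p=0.933). Ribosome biogenesis fell (15 of 40 lower, 25 lower over the list alone, camera adjusted p=4.26e-15 and 0.0163 with an estimated correlation). The secretory list fell (11 of 32 lower, 17 lower over the list alone, camera adjusted p=9.91e-11 and 0.0459 with an estimated correlation). A further 10 lists were called only with the preset correlation. Receptors and effectors were higher among them (9 of 26 higher, 11 higher and 2 lower over the list alone, camera adjusted p=1.25e-05 and 0.101 with an estimated correlation). Stem and progenitor genes were lower (5 of 17 lower, 8 lower over the list alone, camera adjusted p=0.00436 and 0.182 with an estimated correlation), with a fall of Cd34 (log2 -1.78±0.32). By edgeR 916 genes were higher and 403 lower, with a total of 323 without stage II isotype 1, 775 without stage I isotype 2 and 851 without stage I isotype 3. Mpo (0.203) lost the call without stage I isotype 2 or 3 or stage II isotype 1 or 2. Ctsg (0.0841), Amigo2 (0.0996), Serpina3g (0.0564), Rab38 (0.0515) and Cd34 (0.0524) did not pass without stage II isotype 1. Lrrn3 (0.222) lost the call without stage I isotype 2 or 3 or stage II isotype 1. Bhlha15 (0.145) did not pass without any 1 of the 5 libraries. Dmkn (0.0971) lost the call without stage I isotype 3 or stage II isotype 1 or 2.

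From stage II to stage III in isotype mice, S phase genes fell (38 of 42 lower, 41 lower over the list alone, camera adjusted p=2.01e-25 and 0.000702 with an estimated correlation). Ribosome biogenesis fell (33 of 40 lower, 34 lower over the list alone, camera adjusted p=1.26e-17 and 0.0036 with an estimated correlation). The sort markers rose (7 of 9 higher, 7 higher and 1 lower over the list alone, camera adjusted p=3.2e-05 and 0.0179 with an estimated correlation), with Cd200r3 (log2 5.46±1.03, 25.2±12.4 against 0.58±0.341 CPM). Ccr3 rose (log2 3.12±0.40, 443±197 against 50.9±27.9 CPM, edgeR adjusted p=2.62e-05). Other rises were the integrin Itgam (log2 2.44±0.26), the complement receptor C3ar1 (log2 3.29±0.36), the matrix protein Thbs1 (log2 4.57±0.83), Rgs3 (log2 5.33±0.85), Unc5c (log2 4.75±0.84) and Chil5 (log2 4.54±0.94). The endosomal RNA sensor Tlr13 went from 0 counts to 50.5 CPM, at least 272-fold higher against a floor of 3 counts over the group. Samd11 went from 3 counts to 359 (67.6-fold, 95% counting interval 22.9 to 329). Myc fell (log2 -2.82±0.37, 19±4.7 against 134±3.52 CPM, edgeR adjusted p=9.2e-06). Mpo (log2 -4.08±0.95), Prss34 (log2 -4.75), the ER chaperone partner Fkbp11 (log2 -3.65±0.41) and the nucleolar Nop56 (log2 -2.34±0.20) fell. Receptors and effectors were higher (17 of 26 higher, 17 higher over the list alone, camera adjusted p=2.98e-07 and 0.0608 with an estimated correlation) among 11 lists called only with the preset correlation. The totals were 2355 genes higher and 2236 lower.

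From stage III to stage IV in isotype mice, S phase genes fell (34 of 42 lower, 2 higher and 34 lower over the list alone, camera adjusted p=3.85e-42 and 0.000146 with an estimated correlation). G2/M genes fell (2 of 52 higher and 46 lower, 2 higher and 46 lower over the list alone, camera adjusted p=3.46e-54 and 0.00701 with an estimated correlation). Cholesterol synthesis fell (1 of 22 higher and 18 lower, 1 higher and 18 lower over the list alone, camera adjusted p=5.08e-10 and 0.00316 with an estimated correlation). Granule proteins fell (1 of 11 higher and 8 lower, 1 higher and 9 lower over the list alone, camera adjusted p=9.95e-10 and 0.0432 with an estimated correlation), led by Epx (log2 -5.16±0.33, 389±188 against 13900±1670 CPM, adjusted p=1.84e-09). Prg3 (log2 -5.06±0.26), the adhesion molecule Vcam1 (log2 -6.19±0.26), Myb (log2 -4.07±0.29) and the protease Prss57 (log2 -7.01±0.51) fell. The kinase Ttk (at least 135-fold lower), Qrfpr (388-fold lower, 95% counting interval 69.1 to 15400), Muc6 (221-fold, 60.7 to 1830), the basophil protease Mcpt8 (187-fold, 51.3 to 1550), Nek2 (log2 -7.19±0.99), Kif4 (log2 -7.03±1.02) and Crhbp (log2 -6.88±1.06) were among the largest falls. The chemokine Ccl9 rose (log2 6.82±0.44, edgeR adjusted p=1.05e-08, 1140 against 10 CPM, chromosome 11, 83572917 to 83578636). The growth factor receptor Fgfr1 rose (log2 8.24, chromosome 8, 25518759 to 25575718). Other rises were Prr5l (log2 6.67), the sodium-calcium exchanger Slc8a1 (log2 5.95±1.07), Ccr1l1 (log2 5.78±0.88), Cmah (log2 5.77±1.09), C3ar1 (log2 2.87±0.27), Adgre1, which encodes F4/80 (log2 1.35±0.25), Cebpb (log2 1.55±0.27), Bcl2a1a (log2 2.81±0.31), Rhbdl3 (at least 198-fold) and Adamdec1 (at least 171-fold). The totals were 1836 genes higher and 2329 lower, and 10 lists were called only with the preset correlation.

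Under anti-IL5 the same steps gave 900 genes higher and 639 lower, 2450 and 2437, and 1292 and 1659, in turn. The first pair was 725 and 754 with upper-quartile scaling and 507 and 611 with only the 2 groups, so its excess of rises turned. From I to II, Serpinb2 (log2 4.62±0.38), Tinagl1 (log2 4.57±0.52), Retnlg (log2 4.43±0.33), Ankrd33b (log2 3.97±0.65), Thbs1 (log2 3.63±0.84), Alox15 (log2 1.58±0.26) and Ccr3 (log2 2.25±0.40) rose. Cdh1 (log2 -5.52±1.53), Prpf40b (log2 -4.98), Lrrn3 (log2 -4.51), Rhoj (log2 -4.08), Firre (log2 -4.05) and Myc (log2 -2.98±0.37) fell. Ribosome biogenesis fell (23 of 40 lower, 27 lower over the list alone, camera adjusted p=4.98e-18 and 0.00685 with an estimated correlation). The secretory list fell (15 of 32 lower, 19 lower over the list alone, camera adjusted p=7.74e-14 and 0.021 with an estimated correlation). From II to III, Retnla (at least 75.7-fold), Pbld1 (log2 4.66±0.78), Slfn5 (log2 4.50±0.98), Nxpe4 (log2 4.45) and Sbf2 (log2 4.42±0.82) rose. Prss34 (log2 -6.41), Mcpt8 (log2 -5.49±1.00), the recombination helicase Rad54b (log2 -4.45±0.48), Fbxo48 (log2 -4.38±0.87), Fgf3 (log2 -4.31±0.52), Epx (log2 -1.52±0.36, 4700±1410 against 13500±3140 CPM, edgeR adjusted p=0.00193) and the mitotic kinase Aurkb (log2 -3.37±0.28) fell. S phase genes fell in that step (38 of 42 lower, 39 lower over the list alone, camera adjusted p=3.8e-39 and 5.05e-05 with an estimated correlation). G2/M genes fell (1 of 52 higher and 50 lower, 1 higher and 50 lower over the list alone, camera adjusted p=1.19e-36 and 0.029 with an estimated correlation). Ribosome biogenesis fell (27 of 40 lower, 27 lower over the list alone, camera adjusted p=2.97e-10 and 0.029 with an estimated correlation). The sort markers rose (8 of 9 higher, 8 higher over the list alone, camera adjusted p=0.000161 and 0.029 with an estimated correlation). From III to IV, Fgfr1 (log2 7.07), Rhbdl3 (log2 6.72), Bmp7 (log2 6.68), Ccl9 (log2 6.33±0.43) and Slc8a1 (log2 5.53±0.89) rose. Sema4f (at least 510-fold lower), Pif1 (at least 161-fold lower), Qrfpr (122-fold lower, 41.3 to 593), Aspm (log2 -6.61±1.22), Epx (log2 -6.38±0.33, 56.4±29.2 against 4700±1410 CPM, edgeR adjusted p=4.69e-10) and Bcl2 (log2 -3.47±0.40) fell. Granule proteins fell in it (1 of 11 higher and 9 lower, 1 higher and 9 lower over the list alone, camera adjusted p=1.63e-18 and 0.00369 with an estimated correlation). S phase genes fell (3 of 42 higher and 32 lower, 4 higher and 32 lower over the list alone, camera adjusted p=5.33e-22 and 0.00272 with an estimated correlation). G2/M genes fell (1 of 52 higher and 45 lower, 1 higher and 46 lower over the list alone, camera adjusted p=1.26e-47 and 0.0109 with an estimated correlation). Cholesterol synthesis fell (1 of 22 higher and 16 lower, 1 higher and 16 lower over the list alone, camera adjusted p=1.54e-10 and 0.00369 with an estimated correlation). Of these counts, the total of 1539 for I to II was 516 without stage II anti-IL5 1 and 870 without stage I anti-IL5 3. Thbs1 (0.111) lost the call without stage I anti-IL5 3 or stage II anti-IL5 1. Cdh1 (0.177) did not pass without stage I anti-IL5 3 or stage II anti-IL5 1 or 2. Prpf40b (0.0608), Rhoj (0.156) and Firre (0.0758) lost the call without stage II anti-IL5 1. Lrrn3 (0.276) did not pass without stage I anti-IL5 2 or 3 or stage II anti-IL5 1 or 2.

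Fold changes of a step in one treatment followed those in the other, with r = 0.566 (jackknife SE 0.0925) for I to II, 0.609 (0.102) for II to III and 0.638 (0.0478) for III to IV over 12387 genes. Simulated steps identical in both treatments gave means of 0.671, 0.757 and 0.829, and over the 8429 genes with a mean of at least 10 CPM the observed values were 0.804, 0.903 and 0.873, against 0.794, 0.916 and 0.933 in identical simulated steps. The slopes of anti-IL5 on isotype steps were 0.586 (SE 0.248), 0.644 (0.185) and 0.556 (0.0921), against 0.672, 0.752 and 0.832 in identical simulated steps. Over genes of at least 10 CPM they were 0.774, 1.01 and 0.704, against 0.793, 0.916 and 0.934, so the II to III slope turned to above that of identical steps. On the axis between neighbouring stage means (both treatments, from 0 at the earlier to 1 at the later stage), anti-IL5 libraries lay ahead of isotype libraries by 0.299 ± 0.0903 (SE) of a step at stage I, 0.197 ± 0.0429 at stage II and 0.177 ± 0.0481 at stage III, and by -0.0249 ± 0.0197 at stage IV. Exact permutation p = 0.1, p = 0.333, p = 0.1 and p = 0.3, where 0.1 (0.333 at stage II) is the smallest these group sizes allow. Without anti-IL5 1 the stage I value was 0.174. A simulated shift of 0.2 gave 0.156, 0.182 and 0.201 at stages I to III. At stage IV it gave 0.00303 (0.00305 unshifted), so it tests nothing there.

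**Figure D5:**
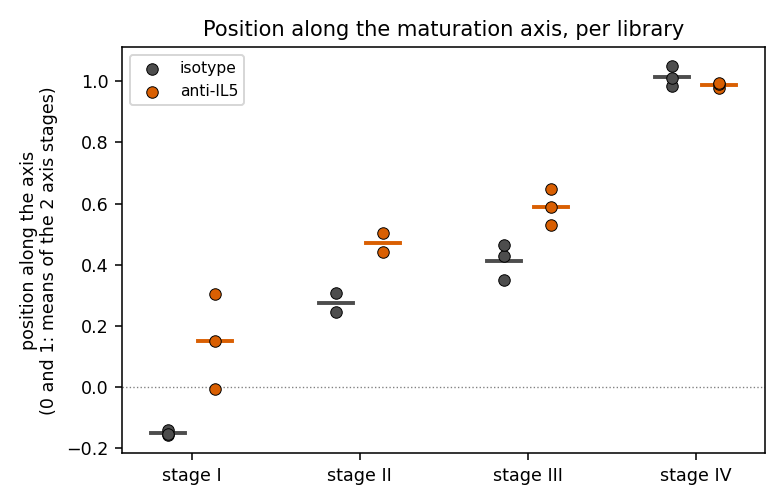
Position of each library (points) and group means (bars) along the maturation axis, by stage and treatment. The axis of each stage runs from 0 to 1 between the means of its neighbouring stages: I to II for stage I, I to III for stage II, II to IV for stage III and III to IV for stage IV.

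Of the genes called both for treatment and along the axis, Ccr3, Id2 and Tgfbi were higher at stage I in the direction of maturation, with 399 of 407 in that direction, 195 of 203 at stage II and 664 of 714 at stage III, but 47 of 108 at stage IV. The treatment effect and the axis step share libraries only at stages I and IV. They had r = 0.39, 0.423, 0.45 and -0.057, and covariances of 0.17, 0.416, 0.514 and -0.0314, where simulations with no effect spanned -0.0336 to 0.0279 for r, -0.0117 to 0.012 for the covariance and 39.8% to 60.2% for the share in the same direction. Independent lists as long would have 73.1, 74.7, 263 and 28.9 genes in the same and 69.4, 73.8, 258 and 27.1 in the opposite direction. No-effect simulations gave 47.2% to 56% at stage I, arguing against shared libraries as a cause. The 50 genes that ran against maturation at stage III included Socs2, Pim1, Cish, Socs1, Bcl2a1a, Bcl2l1 and Lrp12, all lower with anti-IL5, and Serpinb10 and S100a9, both higher. The 61 at stage IV included Socs2, Cish, Bcl2a1a, Bcl2l1, Adra2a, Enah and Xbp1, all lower, and Dhrs3, Il15, Serpinb10 and S100a9, all higher.

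The treatment effect differed between stages for 133 genes by edgeR's interaction test over the 4 stages (1356 at an unadjusted p under 0.05), and between stages III and IV for 79 (67 higher and 12 lower at stage IV; 1265 at an unadjusted p under 0.05). DESeq2 kept the excess of higher calls (202 and 55), but limma-voom gave 22 and 22, and 31 and 26 with a random block. Cpa3 led these (log2 4.76±0.52, edgeR adjusted p=0.000272, chromosome 3, 20215616 to 20242209): it was lower under anti-IL5 at stage III (11.7±2.34 against 212±126 CPM), and at stage IV its level was 12.4±3.03 against 8.27±2.69 CPM. Hs3st1 (log2 4.75±0.89), Tmem215 (log2 3.57±0.48), the DNA repair enzyme Apex1 (log2 2.50±0.42), Gnl3 (log2 2.43±0.38, adjusted p=0.0059), Nkg7 (log2 3.08±0.63) and Calr (log2 1.77±0.34) had a less negative effect at stage IV. Cd300ld (log2 -2.12±0.36), Chn2 (log2 -2.16±0.31), Klra2 (log2 -2.35±0.45), Vmn2r26 (log2 -4.09±0.78), Cd80 (log2 -3.13±0.66), Id1 (log2 -2.08±0.37) and Ear6 (log2 -2.09±0.42) had a more negative one, and Epx (log2 -1.23±0.47, adjusted p=0.308) and Prg2 (log2 -1.41±0.39, adjusted p=0.115) did not pass. S phase genes had a more positive effect at stage IV than at stage III (6 of 42 higher, 21 higher over the list alone, camera adjusted p=7.66e-23 and 0.00172 with an estimated correlation). So did ribosome biogenesis (3 of 40 higher, 10 higher over the list alone, camera adjusted p=1.3e-08 and 0.0412 with an estimated correlation). So did the secretory list (3 of 32 higher, 10 higher over the list alone, camera adjusted p=1.03e-09 and 0.0412 with an estimated correlation). Basophil and mast cell genes did too (2 of 9 higher, 5 higher over the list alone, camera adjusted p=5.83e-13 and 0.00787 with an estimated correlation). Granule proteins had a more negative effect, lost with an estimated correlation (1 of 11 lower, 4 lower over the list alone, camera adjusted p=0.000935 and 0.195 with an estimated correlation). The count of 79 was 50 without stage III isotype 3, 38 without stage IV isotype 2, 46 without stage III anti-IL5 3 and 49 without stage IV anti-IL5 2, and, chosen after seeing the data, 62, 30 and 3 without all isotype libraries numbered 1, 2 or 3 and 49, 5 and 18 without those of anti-IL5. Nkg7 (0.251) lost the call without stage IV isotype 2 or 3 or stage III anti-IL5 2 or 3 or stage IV anti-IL5 2. Cd80 (0.085) did not pass without stage III isotype 1 or stage IV isotype 1 or 2 or 3 or stage III anti-IL5 2 or 3 or stage IV anti-IL5 2 or 3. Ear6 (0.0811) lost the call without stage IV isotype 1 or stage IV anti-IL5 2 or 3. Calr (0.0529) did not pass without stage IV isotype 2 or stage III anti-IL5 3.

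Between stages II and III no single gene passed by edgeR (713 at an unadjusted p under 0.05, 15 by DESeq2 and 0 by limma-voom). Those of smallest p (edgeR adjusted p=0.458) included Spc24 (log2 -1.37±0.28), Cpa3 (log2 -2.68±0.54), Wdr77 (log2 1.17±0.25), Racgap1 (log2 -1.52±0.34) and 2700097O09Rik (log2 -2.02±0.45). S phase genes had a more negative effect at stage III than at stage II (0 of 42 by edgeR, 17 lower at an unadjusted p under 0.05, 8 lower over the list alone, camera adjusted p=3.66e-19 and 0.00403 with an estimated correlation). So did G2/M genes (0 of 52 by edgeR, 34 lower at an unadjusted p under 0.05, 28 lower over the list alone, camera adjusted p=4.37e-33 and 0.0355 with an estimated correlation). Basophil and mast cell genes did too (0 of 9 by edgeR, 5 lower at an unadjusted p under 0.05, 3 lower over the list alone, camera adjusted p=3.86e-08 and 0.0355 with an estimated correlation). Between stages I and II no gene passed (119 higher and 194 lower at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom). Among those of smallest p were Adam19 (log2 -4.69, edgeR adjusted p=0.0845), Id2 (log2 -1.29±0.26, adjusted p=0.456), Cd276 (log2 -8.50, adjusted p=0.81), Tinagl1 (log2 3.00±0.72, adjusted p=1) and Snhg15 (log2 -1.95±0.50, adjusted p=1). Only the interferon response list was called there, higher (0 of 30 by edgeR, 1 higher at an unadjusted p under 0.05, 0 over the list alone, camera adjusted p=0.00107 and 0.9 with an estimated correlation). That call ended with the replicate block (adjusted p=0.809), with fry (0.914) and without isotype number 3 (0.953, lower), absent at stage II. The interaction count was 62 without stage I isotype 2, 58 without stage I isotype 3, 215 without stage II isotype 1, 57 without stage IV isotype 2, 66 without stage I anti-IL5 1, 50 without stage I anti-IL5 2, 66 without stage III anti-IL5 3, 57 without stage IV anti-IL5 2, 66 without stage IV anti-IL5 3 and 215 with a replicate block.

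Sums over lists of other cell types (isotype first) often rested on few genes and need not mark such cells. Azurophil and precursor sums were 8191±1350 and 5397±2870 CPM at stage I and 2049±524 and 1009±103 at stage II. They were 687±198 and 280±17 at stage III, where Calr fell (467 to 118) but Mpo rose (13.1 to 37.3). Stage IV had 208±25 and 286±193. Single anti-IL5 libraries stood out: number 3 at stage I (Mpo 4000 CPM against 700 and 1330, Elane 766 against 34.1 and 63.8) and number 2 at stage IV (Mpo 240 CPM against 40.7 and 16.6). Mature neutrophil sums were 2989±520 and 5004±2380 CPM at stage I and 5438±1400 and 7189±446 at stage II. They were 8319±2100 (Ngp 5190, Retnlg 1910) and 12230±1740 at stage III and 5338±548 (Retnlg 3540, Mmp9 1380) and 8178±575 at stage IV. Of these lists, only basophil and mast cell genes at stage III (1791±451 and 747.5±57.9 CPM) kept a treatment call with an estimated correlation. At stage I their sums were 3219±409 and 2532±583 CPM and monocyte sums 2009±371 and 2310±177. Megakaryocyte sums were 912±132 (Itga2b 885) and 975±252, erythroid sums 193±26.9 and 134±23.7. B lineage (42.2 ± 7.18 and 88.3 ± 22.3 CPM, where Cd79a rose, log2 2.18±0.57), dendritic (60.3 ± 13.6 and 68.4 ± 19.2 CPM) and T, NK and innate lymphoid transcripts (3.07 ± 0.996 and 4.65 ± 1.72 CPM) were lower in level. Cd79a (0.155) lost the call without isotype 1 or 2 or anti-IL5 1 or 2. The smallest camera adjusted p over the 4 stages was 0.196 for monocyte, 0.439 for erythroid, 0.0603 for megakaryocyte and 0.328 for dendritic genes, 0.116 for the sort markers, 0.145 for stem and progenitor genes, 0.485 for proapoptotic genes and 0.0996 for IL-33/NF-kB genes. Sex-linked genes, a check for mixed-up samples, had no list call (smallest camera adjusted p = 0.225), and over the stages Eif2s3y, of 4 tested, rose (log2 0.33±0.08, adjusted p=0.00401).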

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

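Differences between stages, list tests, counts without 1 library, the library size test and the share of transcripts near their lowest level were fixed before. The other tests here were chosen after the result was seen. The first group of results is a difference of the treatment effect between stages, by a test of that difference. It covers 133 genes in the stage by treatment interaction and 79 genes between stages III and IV, with 1 gene list called between stages I and II, 5 between II and III and 14 between III and IV. With an estimated correlation 0, 3 and 4 of these list calls held. The genes with the largest log2 differences between stages III and IV were Cpa3 (4.76), Hs3st1 (4.75), Tmem215 (3.57), Nkg7 (3.08) and Apex1 (2.50) on the higher side and Vmn2r26 (-4.09), Cd80 (-3.13), Klra2 (-2.35), Chn2 (-2.16) and Cd300ld (-2.12) on the lower side.

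For the difference between stages III and IV, 2 of 100 splits of the libraries within stages, the real one included, gave as many genes (79, highest other 84). These splits part paired isotype libraries of stages III and IV, so they do not decide on chance. With whole replicate numbers exchanged, 1 of 10 splits gave as many (highest other 1), too few splits for a share under 5%. Technical sources remain open. Little room for a further fall could account for some transcripts: of the 66 genes with a less negative effect at stage IV, 59.1% had an isotype level there at or below their anti-IL5 level at stage III. The share was 42.6% of 566 other genes lower at stage III (Fisher p = 0.0126) and 49.7% of all other genes. The 66 genes had a median in isotype libraries at stage IV of 4.06 CPM, above the floor of 0.203 to 0.419 CPM, so this stays open, as does a biological difference, not tested apart from it. The count also rests on single libraries: it was 50 without isotype stage III replicate 3 and 38 to 49 without 1 of 3 others. It fell to 3 without the isotype libraries numbered 3, but also to 5 without the anti-IL5 libraries numbered 2, so the fall cannot be told apart from a loss of libraries.

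The second pattern is that anti-IL5 libraries lay further along the maturation axis at stages I to III, by 0.224 ± 0.037 (SE) on average. Library size is argued against, since thinning every library to the total of the smallest gave 0.229 ± 0.0371. Mature neutrophil RNA as the whole source is argued against. With a 5-gene index as covariate the difference was 0.259±0.044, against 0.228±0.0405 without (16 libraries). Neutrophil precursor RNA was untested. Whether the gates took in cells further along in anti-IL5 mice cannot be told apart from a change within cells: sort marker transcripts moved toward the later stage in 17 of 21 tests, by a median of 0.127 of their step, with Pira2 at 0.785 and Pirb at 0.722 at stage I but Cd55 at -1.01 at stage II and Kit at -0.341 at stage III, and protein levels at the gate were not used here. Earlier maturation under IL-5 blockade, the biological reading, therefore stays a hypothesis.

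The third pattern is a higher level of mature neutrophil transcripts in anti-IL5 libraries at stages III and IV. Both list calls were lost with an estimated correlation. Ltf, Camp, Lcn2, S100a8 and S100a9 summed to 1890 ± 657 CPM against 854 ± 331 in isotype libraries at stage III and to 659 ± 229 against 185 ± 59.3 at stage IV (exact permutation p = 0.1, the smallest possible). These 5 genes, chosen after seeing the data, had log2 ratios between 1.66 and 2.04 at stage IV, and only S100a9 passed by edgeR at either stage. Neutrophil RNA in the libraries would give a single shared ratio for genes that eosinophils lack. Over all 14 genes the log2 ratios at stage IV ran from -1.07 (Cxcr2) to 2.04 (Ltf). Their SD was 0.909 (mean standard error 0.609), but they include Retnlg (3540 CPM in isotype libraries). At stage I all 14 were above 0 (SD 0.655 against 0.617) and the list was called only with the preset correlation. The 5 genes did not part the groups (2390±1210 against 1460±237 CPM, exact permutation p = 0.4). At stage II 9 of 14 were above 0 (SD 0.917 against 0.729) and the 5 genes were level (1970 against 1920 CPM). At stage III 13 of 14 were above 0 (SD 0.631 against 0.588). The 5 genes had SDs below their standard errors at stages III (0.315 against 0.626) and IV (0.17 against 0.635), as 1 ratio would give. Chosen after the fact, they cannot tell neutrophils left after Ly6G depletion from a rise inside eosinophils.

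For comparisons of 3 against 3 libraries the splits are too few for a share under 5%: 1 of 10 splits gave as many genes as the real one for treatment at stage I (548, highest other 0), stage III (789, highest other 1) and stage IV (130, highest other 1) and for the step from III to IV in isotype (4165, highest other 0) and anti-IL5 mice (2951, highest other 0). The same holds for the mean over stages when whole replicate numbers are exchanged (1 of 10; 2343, highest other 348) and for the interaction (1 of 10; 133, highest other 23). With libraries exchanged within stages, 1 of 100 splits gave as many genes as the mean over stages (2343, highest other 229), and 8 of 100 at least the 133 genes of the interaction (highest other 283), but these splits too part paired libraries and do not decide.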

How the results depend on the processing

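The fits without all libraries of 1 number were chosen only after the data were seen; all other alternatives in this part were fixed before. No call on a named gene or list turned into a call the other way in an alternative. With DESeq2, 813 of 821 calls on named genes were kept, 803 with the replicate block, 811 with median-ratio scaling, 807 with upper-quartile scaling, 787 of 789 with the stricter filter, 752 with no filter, 757 with the random block, 683 with limma-voom, 483 with glmTreat, 578 of 688 with only the 2 groups, 430 of 534 without isotype libraries numbered 3 and 5321 of 6214 with 1 library left out. Depth limits transcripts under about 1 CPM, and groups of 2 limit stage II. The cause of the values that follow was not tested, but glmTreat asks for a larger change and fewer libraries hold less information. Totals of genes called moved by more than 1.5 times as follows. DESeq2: stage I 989 (513 higher, 476 lower), II 472, III 1311, IV 256, difference II minus I 3, III minus II 15, IV minus III 257, interaction 518. Limma-voom: I 1694, II 12, IV 323, step I to II isotype 623, difference IV minus III 44. glmTreat: I 72, II 16, III 144, IV 48, mean 132, isotype steps 260, 2217 and 2000, anti-IL5 steps 320, 2688 and 1229, difference IV minus III 8. Only the 2 groups: I 1123, II 1, III 496, isotype steps I to II 687 and II to III 2951. Without isotype libraries numbered 3: I 348, III 286, isotype step III to IV 2632, difference IV minus III 3, interaction 38, lists of the difference III minus II 11 (97 of 106 list calls kept). The difference IV minus III was 30 without isotype number 2 and 49, 5 and 18 without anti-IL5 number 1, 2 or 3. Where 1 direction led, it turned for stage I with limma-voom (775 higher, 919 lower), the random block (346, 438) and only the 2 groups (532, 591), for stage II without isotype 1, for the anti-IL5 step I to II with upper-quartile scaling and only the 2 groups, and for the steps II to III, near 50% in each treatment, with median-ratio scaling (2199 and 2403 isotype, 2173 and 2666 anti-IL5), upper-quartile scaling, DESeq2 and limma-voom, and under anti-IL5 also with no filter, with glmTreat, without stage II anti-IL5 1 (1710, 1866) and without stage III anti-IL5 2 (2113, 2124). Random block: IV 212, interaction 354. The replicate block moved the interaction to 215 and the list count of the difference II minus I to 8 (all lower) and no other count by that much (stages 726, 286, 1019 and 181, mean 2630). Apart from stages III and IV in isotype mice, libraries share only a number: pair correlations ran from 0.013 to 0.34, 21 of 22 libraries correlated best with their own number, a hint from the data and not the design, and the random block correlation was 0.107.

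Leaving out 1 library gave 184 to 445 genes at stage I, 40 to 423 at II, 3.1e2 (36 higher, 272 lower) to 843 at III, 68 to 116 at IV, 2021 to 2549 for the mean, 323 to 1736, 3564 to 4651 and 3231 to 3858 for isotype steps, 516 to 1497, 3576 to 4621 and 2106 to 2477 for anti-IL5 steps, 0 to 1, 0 to 2 and 38 to 85 for the differences and 50 to 215 for the interaction. A single gene was called in the difference II minus I without stage I anti-IL5 3 and in III minus II without stage II isotype 1, and 2 without stage II anti-IL5 2. Step correlations ran from 0.461 to 0.564, 0.491 to 0.617 and 0.586 to 0.636, slopes from 0.406 to 0.688, 0.478 to 0.681 and 0.504 to 0.592, and axis differences from 0.174 to 0.354, 0.166 to 0.226, 0.145 to 0.207 and -0.0584 to 0.00138. Over genes of at least 10 CPM the step correlations were 0.804, 0.903 and 0.873 and the slopes moved to 1.01 (II to III) and 0.704 (III to IV). Lists called with an estimated correlation were 2, 2, 5 and 4 at stages I to IV, 3 for the mean, 2, 3 and 4 for isotype steps, 2, 4 and 4 for anti-IL5 steps and 0, 3 and 4 for the differences, so 109 of 151 list calls ended. With fry the moved counts were 4 at II, 5 at III, 4 at IV, 17 and 14 for anti-IL5 steps II to III and III to IV, and 0, 1 and 4 for the differences; median-ratio scaling gave 2 lists for II minus I.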

Other observations

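These interferon values were chosen after the result was seen. Isotype libraries numbered 3 were highest of their group for 25, 28 and 28 of 30 interferon-induced genes at stages I, III and IV. These genes summed to 474, 501 and 1070 CPM in isotype libraries 1 to 3 at stage I and 1020, 1310 and 3010 CPM at stage III. Number 3 over the mean of the others was 2.2, 2.59 and 2.61, against 1.06, 1.07 and 0.934 under anti-IL5. Without isotype number 3, preset-correlation camera adjusted p for the list's rise under anti-IL5 fell from 0.345, 0.0526 and 0.00506 to at most 5.54e-11. List genes moved together, so these p may be too small.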
